A study of Homo sapiens with 6 samples.

How the data were processed

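Messenger RNA of cells labelled as Hep3B with acquired sorafenib resistance was sequenced in 6 libraries, 3 wildtype (control) and 3 STIM1 knockout. Per the labels' protocols, RNA was extracted with a column kit, 1 µg of total RNA went into each library, and libraries were made with a SMARTER mRNA-Seq kit. The groups come from the sample titles. The genotype field names STIM1, STIM2 and STIM3 knockout over the 3 samples, while the titles and the series text give a single STIM1 knockout group. The submitters' processing notes name only GRCm38 and mm10, which are mouse builds, whereas the chromosome accessions in the deposited table are those of human GRCh38, and coordinates are given in that build. Of 16335 gene symbols on the main chromosomes, 16053 matched the reference annotation of GRCh38.p14 by symbol and chromosome, and 97.7% of these started within 5000 bases of it.

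The deposited table gives, per the file headers, the signal of each gene as a mean over each group of size-factor-normalized read counts made by the authors, with no value per library. The ratio (fold change) of the group means, knockout over control, was deposited by the authors, as was its log2 value, without shrinkage and infinite where a group is at 0. The p-value and adjusted p-value of the authors' comparison are deposited beside them, in columns that per the file headers are those of the DESeq format. The adjusted p equals a Benjamini-Hochberg adjustment over the 17381 listed genes to within 1.3e-15. Neither the aligner nor the counting tool is stated. A companion table repeats 6 columns of the first and was not used. Genes on alternate loci have entries of their own, so a gene with such a copy may have its reads divided, and it is called uncertain where named.

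With no value per library, the comparison is the authors' own, at an adjusted p under 0.05, as fixed before the data were examined for such a table. What follows was chosen after seeing the data. The printed means carry 15 digits, and a mean of 3 whole counts, each divided by its own size factor, leaves a pattern in them that was searched for the counts. Reads were settled for 17379 of 17381 genes, while GAPDH and EEF1A1 were not settled. Means recomputed from the reads differed from the deposited means by at most 5.1e-11, which the search requires, and recomputed size factors by at most 0.0074%. For 4 control and 68 knockout means several sets of reads fitted, and the set with its libraries nearest each other was taken. Above a mean of 60, sets with each library within 50% of the mean were sought first. Both choices favour a small SD. Within a group the libraries have no sample number and are called A, B and C. The SD over 3 libraries and limma's SE rest on these reads. The libraries held 11869673 to 16120012 reads, and a group at 0 was given a floor of 3 reads over the group. With 1 to 3 reads, the ratio is given with its 95% counting interval.

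The limma test (version 3.58.1 in R 4.3.3, empirical Bayes with trend, Benjamini-Hochberg adjustment) ran on log2(normalized count + 1) of genes with a mean of at least 1. Gene lists were tested with camera of limma on these values, with a preset correlation of 0.01 and adjustment over the lists. The plan named voom values for counts, and log2 values if there were no counts. The deposit held no counts, and voom values of the recovered reads were run as an alternative. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in a single direction without comparing them with other genes, were run beside it. The 36 lists were fixed before the data were examined. They cover store-operated calcium entry, calcium pumps and store proteins, calcineurin-NFAT targets, ferroptosis defence and drivers, NRF2 targets, the ATF4 response, endoplasmic reticulum stress chaperones, glycolysis, hypoxia, oxidative phosphorylation, fatty acid oxidation and synthesis, cholesterol synthesis, hepatocyte and fetal liver markers, mesenchymal and epithelial genes, drug efflux, MAPK feedback, receptor tyrosine kinases, WNT targets, cell cycle, apoptosis, autophagy and lysosome, interferon, NF-kB, AP-1, heat shock, metallothioneins, fibroblast, endothelial, blood and immune, and kidney and neuronal markers, mitochondrially encoded genes and ribosomal proteins. Of these, 35 had at least 5 tested members, and 5 were called. None of the 5 calls held with an estimated correlation. Medians of a list are of the deposited log2 changes with groups at 0 held at the floor, and means are of limma's.

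Named genes follow a rule fixed before the data were examined. It takes STIM1, STIM2, ORAI1, ORAI2 and ORAI3, and the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 and no overlap between groups. It adds the 2 members of smallest p from each list, and SLC7A11, GPX4, AFP and ALB. Genes that the rule or a list also takes but that are not named are not reported here. Other genes are said to be chosen after their values were seen. The KEGG pathways of the reference, of 10 to 300 genes, were tested with camera. Gene order along chromosomes was tested in windows of 21 genes with a mean of at least 20 against 200 shuffles of gene order. Zinc finger genes on chromosome 19 were told by their symbols, a split also chosen after seeing the data.

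The steps were tested on simulated data, with reads drawn from each gene's mean over all 6 libraries and the library sizes. A known fold changed 200 genes, and 15252 genes passed the filter. Recovery settled 99.99% of control means and 100.0% of knockout means. The limma step found 86.8% of genes changed 1.5-fold, 93.7% changed 2-fold and 95.7% changed 4-fold, and 0 changed genes were called in the wrong direction. Of 203 called genes, 12 belonged to a list raised on purpose and 7 were unchanged. The raised list was called and 0 of 34 other lists were. Genes were drawn independently with a common dispersion and few were changed, against 54.5% called in the real data. The simulation therefore does not show how often camera calls lists falsely there. Alternatives changed the threshold, test, scaling, pseudocount, low-count filter and treatment of copies, or left out each library in turn. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.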

Results

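RNA sequencing was done on cells labelled as Hep3B, a human liver carcinoma line, with acquired resistance to sorafenib. Sorafenib is a kinase inhibitor used against liver cancer. The labels give 6 libraries in 2 groups, 3 from wildtype cells (called control here) and 3 from cells in which STIM1, the calcium sensor of the endoplasmic reticulum, had been knocked out, and state no treatment. The deposited table holds group means of normalized read counts for 17381 genes and no value per library. Whole reads per library were recovered from the digits of those means for 17379 genes. The libraries cannot be matched to sample numbers and are called A, B and C by falling size factor. The control libraries held 16120012, 14689788 and 13623044 reads, and the libraries labelled knockout held 14879697, 14485599 and 11869673, without the 2 genes not recovered (GAPDH and EEF1A1). The median coefficient of variation was 2.87% over 3873 genes of the control libraries and 2.68% over 3789 genes of the libraries labelled knockout, each set having a mean of at least 1000. The comparison asks which transcripts differ after STIM1 knockout in resistant cells. Below, "rose" and "fell" refer to libraries labelled STIM1 knockout against control and to an adjusted p under 0.05 in the authors' deposited table. Levels are normalized read counts with the SD over the 3 recovered libraries of a group, and log2 changes with a standard error (SE) are limma's on the recovered libraries unless the authors' table is named. PCR reads carried no molecular identifiers, so read floors and counting intervals cover counting error only. SDs, SEs and limma p-values measure the spread between libraries of a group. The sample titles do not say whether these came from separate cultures or clones.

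STIM1 itself was higher, not lower, in the libraries labelled STIM1 knockout. The STIM1 gene (chromosome 11, 3854604 to 4093210, GRCh38) had 1047, 972 and 836 normalized reads in control libraries A, B and C and 1454, 1439 and 1422 in the libraries labelled knockout. The means were 951 ± 107 and 1438 ± 16.1 (SD, n = 3), a log2 change of 0.60 (SE 0.06, limma adjusted p = 8.90e-07). The authors' deposited table gave the same log2 change of 0.60 with an adjusted p of 4.33e-14. The transcript level therefore goes against the label, and each direction below is that of libraries labelled STIM1 knockout. An edit that shifts the reading frame can leave the transcript in place, so the gene total says nothing of the protein, and it does not show which exons the reads cover.

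**Figure D1:**
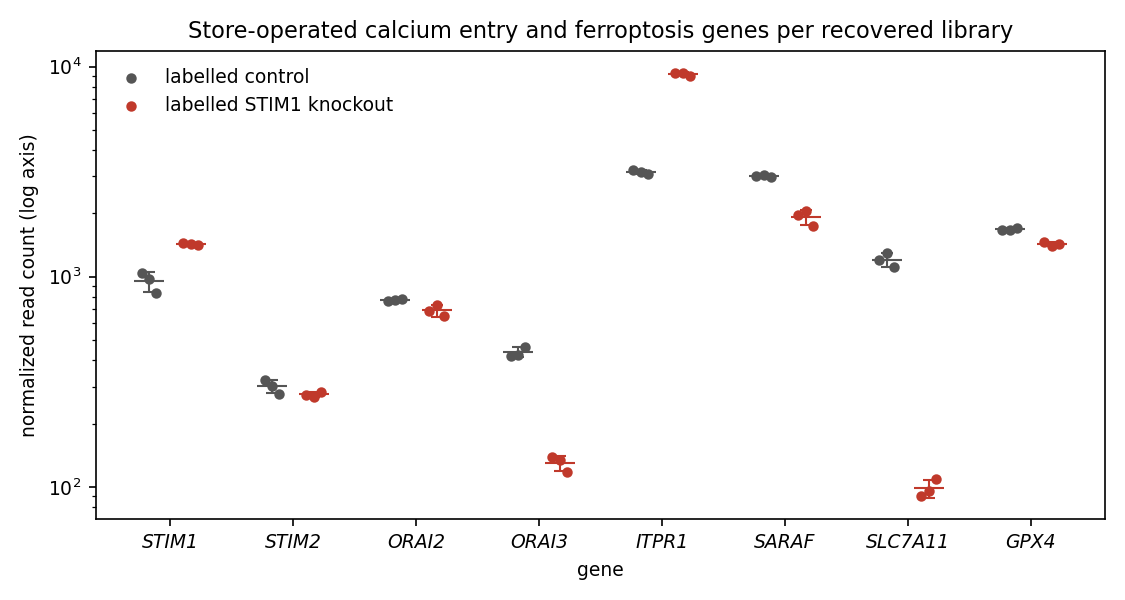
Normalized read counts (log axis) of 8 genes of calcium entry and ferroptosis in each recovered library, with the mean and SD of 3 libraries per group as bars. STIM1 lies at 951 in control and 1438 in libraries labelled knockout, SLC7A11 at 1203 and 98.6.

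Genes of store-operated calcium entry moved apart from each other. ITPR1, a calcium release channel of the endoplasmic reticulum, rose from 3150 ± 74.0 to 9256 ± 171 (SD, n = 3), a log2 change of 1.55 (SE 0.03). ORAI3, a pore subunit of the plasma membrane channel that STIM1 opens, fell from 437 ± 23.7 to 130 ± 10.8, a log2 change of −1.75 (SE 0.10). SARAF, which slows this calcium entry, fell from 3021 ± 46.5 to 1921 ± 156, a log2 change of −0.66 (SE 0.05). ORAI2 fell from 775 ± 5.53 to 690 ± 44.4 with an adjusted p of 0.0468 in the authors' deposited table, and the call was lost at a threshold of 0.01 and, under limma, without library C labelled knockout (adjusted p = 0.0828, range over its alternatives 0.00601 to 0.0828). STIM2 averaged 301 ± 22.7 and 275 ± 7.31 (adjusted p = 0.322 in the authors' deposited table). ORAI1 shares its reads with a copy on an alternate locus and is uncertain. Summed over both copies, it averaged 88.8 and 80.6 (limma adjusted p = 0.417). Of 19 measured genes of the list, 5 rose, 7 fell and 7 did not pass, with the same 5 and 7 when adjusted over the list alone. The camera test of the list gave an adjusted p of 0.831, directed down, with a median log2 change of 0.02 and a mean of −0.23.

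Other calcium genes included 6 that rose and 12 that fell among 24 calcium pumps and store proteins, also when adjusted over the list alone (camera adjusted p = 0.344). ATP2B4, a plasma membrane calcium pump, fell from 6711 ± 220 to 3690 ± 89.6 (log2 change −0.86, SE 0.03). CANX, an endoplasmic reticulum chaperone, shares reads with an alternate copy. It had a log2 change of 1.19 on its main copy and 0.29 (SE 0.04) when both copies were summed, so its size is uncertain. Among 20 calcineurin-NFAT targets and feedback genes, 9 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.121, directed up). With the stricter filter the list passed (adjusted p = 0.0455, range over its camera alternatives 0.0455 to 0.584). The nuclear receptors NR4A1, from 360 ± 21.6 to 1007 ± 41.7, and NR4A3, from 192 ± 13.2 to 610 ± 4.73, rose.

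Across the genome, the authors' deposited table placed 9472 of 17381 genes (54.5%) under an adjusted p of 0.05. Of these, 4472 were higher and 5000 lower in libraries labelled knockout. With a log2 change of at least 1 as well, 2979 genes remained, 1080 higher and 1899 lower, so the larger changes leaned further towards loss. Over all 17379 genes with recovered reads, the groups did not overlap in 10955 (63.0%), where chance gives 10%. Losses were more complete than gains. A mean of at least 300 in control with at most 3 in the libraries labelled knockout was found for 45 genes, and the opposite for 0 genes. Of genes with at least 100 in the higher group and under 5% of it in the other, 216 were lower and 1 was higher in the libraries labelled knockout. The limma test on recovered libraries called 10430 genes.

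The 6 largest falls by the rule for named genes had 0 reads in all 3 libraries labelled knockout, because the rule sorts on the deposited log2 ratio, which is infinite there. The order is therefore not a ranking against genes with a few reads left. KYNU, an enzyme of tryptophan breakdown chosen after its values were seen, went from 18616 reads to 1, a ratio of 17300 with a 95% counting interval from 3100 to 683000. Against a floor of 3 reads over the group, GALNT6, a glycosyltransferase that starts mucin-type O-glycans, fell from 3049 ± 74.4 (SD, n = 3) by at least 2960-fold. The amino acid transporter SLC6A15 fell from 1795 ± 34.4 by at least 1740-fold. The acetylcholine receptor subunit CHRNA9 was at least 968-fold lower, the EGF receptor ligand EPGN at least 801-fold lower, the scaffold protein gene MPDZ at least 750-fold lower and ABLIM3 at least 561-fold lower. Rises began from low levels. The homeobox gene ANHX had 0 reads in control and 16.8 ± 8.59 in libraries labelled knockout, at least 17.5-fold higher. TM4SF4 was 60.8-fold higher, with a 95% counting interval from 16.5 to 508. The actin-bundling protein gene LCP1 rose from 7.58 ± 1.97 to 246 ± 3.03, a log2 change of 4.87 (SE 0.22). OLAH rose from 2.80 ± 1.39 to 87.1 ± 5.20 and PSAPL1 from 1.60 ± 0.572 to 39.8 ± 9.37. MYOM2 rose too, but shares reads with an alternate copy. Summed over both copies it went from 4.54 to 62.1, a log2 change of 3.92 (SE 0.51).

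**Figure D2:**
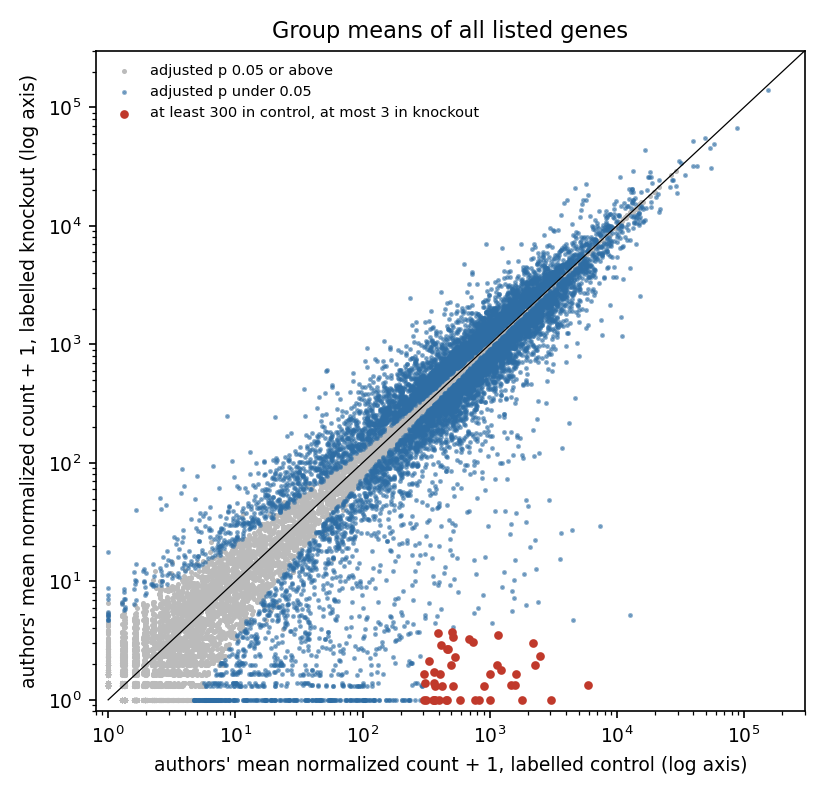
Mean normalized count plus 1 of each listed gene in control (x, log axis) and in libraries labelled knockout (y, log axis), from the authors' deposited table, with genes under an adjusted p of 0.05 in blue. The 45 red points, at least 300 in control and at most 3 in libraries labelled knockout, have no counterpart on the other side of the diagonal.

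Mesenchymal and invasion genes were lower and epithelial junction genes higher in the libraries labelled knockout. Of 25 measured mesenchymal and invasion genes, 16 fell and 5 rose, also when adjusted over the list alone, with a median log2 change of −1.52 (camera adjusted p = 0.032, but adjusted p = 0.436 with an estimated correlation). MMP2, a collagenase of basement membranes, fell from 2487 ± 176 to 1.36 ± 0.487 (SD, n = 3). ITGA5, the alpha subunit of the fibronectin receptor, fell from 12732 ± 237 to 4423 ± 184, a log2 change of −1.53 (SE 0.03). FN1, the gene of fibronectin itself, was chosen after its values were seen and went from 7401 to 28.3 in the authors' deposited table. The 5 members that rose, likewise named after their values were seen, were the transcription factors ZEB1 and SNAI2, the collagen gene COL1A1 and the matrix proteins CCN1 and CCN2. Of 20 epithelial junction genes, 12 rose and 1 fell, also when adjusted over the list alone, with a median log2 change of 0.33 (camera adjusted p = 0.0179, but adjusted p = 0.436 with an estimated correlation). CGN, the tight junction protein cingulin, rose from 1189 ± 23.6 to 2670 ± 30.0, and KRT8, a keratin of simple epithelia, from 18157 ± 490 to 28617 ± 591. The member that fell was ESRP1, a splicing regulator of epithelial cells, named after its value was seen.

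Interferon-stimulated genes were lower as a group. Of 26 measured, 17 fell and 5 rose, also when adjusted over the list alone, with a median log2 change of −1.09 (camera adjusted p = 0.0179, but adjusted p = 0.436 with an estimated correlation). OASL, of the oligoadenylate synthetase family, fell from 8880 ± 283 to 2135 ± 29.4 (SD, n = 3), a log2 change of −2.06 (SE 0.03). IFIH1, the sensor MDA5 of double-stranded RNA, fell from 563 ± 25.9 to 7.18 ± 2.32, a log2 change of −6.15 (SE 0.21). The 5 that rose were ISG15, ISG20, OAS1, OAS3 and USP18, named after their values were seen. USP18 and ISG15 encode a protease and the ubiquitin-like protein it removes. Markers of blood and immune cells were 4 lower and 1 higher among 15 measured, or 2 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.344). Of these markers, the lysosomal protein gene CD68, from 915 ± 15.8 to 58.4 ± 1.52, fell, and CD8A, from 25.2 ± 6.08 to 104 ± 4.92, rose.

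Genes of the ATF4 and amino acid response were lower in the libraries labelled knockout, with 15 of 26 fallen and 4 risen. Adjusted over the list alone, 16 fell and 4 rose. The median log2 change was −0.61 (camera adjusted p = 0.032, but adjusted p = 0.436 with an estimated correlation). PHGDH, the entry enzyme of serine synthesis, fell from 4007 ± 72.1 to 711 ± 36.3 (SD, n = 3), a log2 change of −2.49 (SE 0.04). ALDH1L2, a mitochondrial folate enzyme, fell from 1733 ± 64.6 to 161 ± 39.8. The 4 that rose, named after their values were seen, were the transcription factor ATF3, the amino acid transporter subunits SLC7A5 and SLC3A2, and the lipoprotein receptor VLDLR. Endoplasmic reticulum stress chaperones split into 6 that rose and 11 that fell of 19, also when adjusted over the list alone (camera adjusted p = 0.565). Of these, DNAJC3 rose from 818 ± 8.32 to 1630 ± 42.1 and PDIA4 fell from 6604 ± 182 to 4301 ± 19.4.

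Cell cycle and proliferation genes were lower by small amounts. Of 32 measured, 21 fell and 3 rose, also when adjusted over the list alone, with a median log2 change of −0.26 (camera adjusted p = 0.0355, but adjusted p = 0.436 with an estimated correlation). The call was lost without library B (adjusted p = 0.053) or library C (adjusted p = 0.0563) labelled knockout, within a range of 0.00558 to 0.436 over its camera alternatives. MCM4, a subunit of the replicative helicase, fell from 6429 ± 124 to 3859 ± 69.5 (SD, n = 3), and TOP2A, a topoisomerase of dividing cells, from 16082 ± 311 to 10730 ± 120. The 3 that rose, named after their values were seen, were the phosphatase gene CDC25A, the survivin gene BIRC5 and the transcription factor gene MYBL2. Apoptosis regulators comprised 14 that rose and 7 that fell of 26, or 14 and 8 when adjusted over the list alone (camera adjusted p = 0.23). The initiator caspase gene CASP9 rose from 727 ± 14.3 to 2156 ± 78.5, and the survival gene MCL1 fell from 11050 ± 139 to 6647 ± 154.

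**Figure D3:**
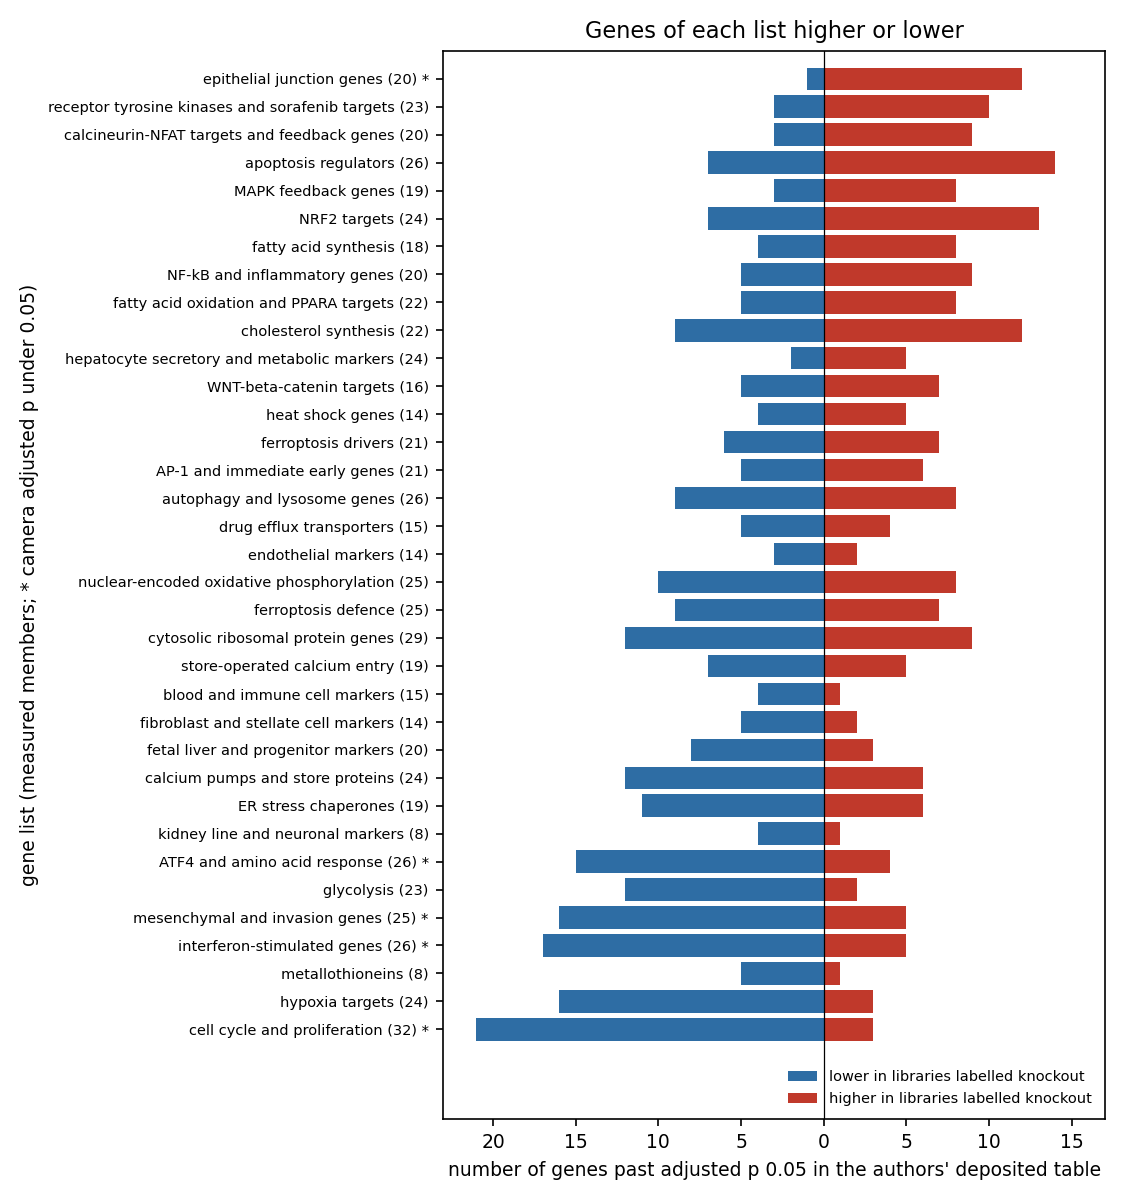
Number of genes of each fixed list that were higher (right) or lower (left) in libraries labelled knockout at an adjusted p under 0.05 in the authors' deposited table, with measured members in parentheses and an asterisk where camera's adjusted p was under 0.05. Of 32 cell cycle and proliferation genes 21 fell, and of 20 epithelial junction genes 12 rose.

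Hypoxia targets held some of the deepest losses, although the list did not pass on log2 values. Of 24 measured, 16 fell and 3 rose, or 17 and 3 when adjusted over the list alone, with a median log2 change of −0.38 (camera adjusted p = 0.0552). The list passed without control library B (adjusted p = 0.0447) or C (adjusted p = 0.0323) and with the stricter filter (adjusted p = 0.0348). It also passed with voom values (adjusted p = 0.0136), the form planned for counts, on reads recovered after seeing the data. Its camera alternatives ranged from 0.0136 to 0.687. The carbonic anhydrase CA9 fell from 2393 ± 177 to 5.68 ± 2.74 (SD, n = 3), a log2 change of −8.57 (SE 0.23), and CA12 from 2084 ± 104 to 18.5 ± 4.98, a log2 change of −6.77 (SE 0.15). In glycolysis, 12 of 23 genes fell and 2 rose, or 13 and 2 when adjusted over the list alone (camera adjusted p = 0.121). With voom values the list passed (adjusted p = 0.0208, range over its camera alternatives 0.0208 to 0.695). Hexokinase HK1 fell from 4094 ± 56.4 to 1256 ± 5.70 and enolase ENO1 from 54876 ± 1010 to 30471 ± 777. Of 8 metallothioneins and related metal genes, 5 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.0873). MT1E fell from 496 ± 25.7 to 83.9 ± 4.17 and MT1X from 622 ± 67.2 to 86.0 ± 10.8.

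Genes that protect against ferroptosis, the iron-dependent form of cell death, moved both ways. SLC7A11, the cystine importer that feeds glutathione synthesis, fell from 1203 ± 95.8 to 98.6 ± 9.74 (SD, n = 3), a log2 change of −3.60 (SE 0.09, limma adjusted p = 5.92e-14). GPX4, which reduces lipid peroxides, fell from 1681 ± 25.2 to 1433 ± 33.0, a log2 change of −0.23 (SE 0.04). The GPX4 gene lies among 58 neighbouring genes on chromosome 19, from ABCA7 to TLE6, whose median log2 change was −1.21. AIFM2, a ubiquinone reductase that acts beside GPX4, rose from 965 ± 21.8 to 2404 ± 82.8, and the transferrin receptor TFRC from 16723 ± 674 to 43553 ± 271. TFRC brings iron into the cell and stands on both the defence and the driver list. Of 25 defence genes, 7 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.905, directed up, with a median of −0.02). Of 21 driver genes, 7 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.877, directed up, with a median of −0.09 and a mean of −0.15). ACSL4, which loads membranes with oxidisable fatty acids, fell from 2881 ± 130 to 623 ± 48.6, and the polyamine enzyme SAT1 from 5687 ± 237 to 1946 ± 95.8.

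NRF2 targets, the genes of the antioxidant response, rose more often than they fell, but those that fell did so more deeply. Of 24 measured, 13 rose and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.275, directed up, with a median of 0.25 and a mean of −0.75). The aldo-keto reductase AKR1C1 fell from 1478 ± 76.4 to a single read (SD, n = 3), a ratio of 4300 with a 95% counting interval from 771 to 170000. AKR1C3 fell from 1509 ± 56.6 to 7.36 ± 1.95. Of 15 drug efflux transporters, 4 rose and 5 fell, or 5 and 5 when adjusted over the list alone (camera adjusted p = 0.684). ABCC4 rose from 640 ± 23.2 to 1289 ± 30.2, and ABCG2 fell from 165 ± 15.8 to 24.7 ± 10.9.

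In each of the growth signalling and inflammatory lists more genes rose than fell, and none of the lists passed camera with the default filter. Of 23 receptor tyrosine kinases and sorafenib targets, 10 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.125). FGFR3 rose from 751 ± 30.7 to 1511 ± 29.5, and AXL fell from 1057 ± 46.4 to 335 ± 30.5 (SD, n = 3). Of 19 MAPK feedback genes, 8 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.157), with CCND1 up from 1574 ± 38.7 to 2747 ± 26.6 and PHLDA1 down from 585 ± 35.2 to 234 ± 31.8. Of 16 WNT-beta-catenin targets, 7 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.536), with GLUL up from 947 ± 37.0 to 1882 ± 65.6 and TBX3 down from 2882 ± 89.9 to 1399 ± 79.6. NF-kB and inflammatory genes had 9 of 20 risen and 5 fallen, also when adjusted over the list alone (camera adjusted p = 0.373, directed up, with a median of 0.11 and a mean of −0.10). With the stricter filter the list passed (adjusted p = 0.0379, range over its camera alternatives 0.0379 to 0.687). NFKB2 rose from 1871 ± 71.5 to 4214 ± 68.0. Of 21 AP-1 and immediate early genes, 6 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.344), with KLF4 up from 1276 ± 23.5 to 2031 ± 37.8 and JUNB down from 3561 ± 86.4 to 1904 ± 72.3.

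Lipid genes changed singly more than as groups. Among genes of fatty acid oxidation and PPARA targets, PDK4, which restrains pyruvate oxidation, rose from 715 ± 23.3 to 2487 ± 120, and the coactivator PPARGC1A from 341 ± 5.33 to 1146 ± 26.2 (SD, n = 3). Of these 22 genes, 8 rose and 5 fell, or 8 and 6 when adjusted over the list alone (camera adjusted p = 0.576, directed up, with a median of 0.07 and a mean of −0.11). In fatty acid synthesis, 8 of 18 rose and 4 fell, or 9 and 4 when adjusted over the list alone (camera adjusted p = 0.561, directed up, with a median of 0.07 and a mean of −0.22). The elongase ELOVL6 fell from 359 ± 10.8 to 10.2 ± 2.06 and SREBF1 from 5038 ± 111 to 3031 ± 50.5. In cholesterol synthesis, 12 of 22 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.364). HMGCS1 rose from 1631 ± 24.8 to 3617 ± 42.9. Autophagy and lysosome genes had 8 risen and 9 fallen of 26, or 8 and 10 when adjusted over the list alone (camera adjusted p = 0.656). The lysosomal protease CTSD fell from 6631 ± 39.2 to 2586 ± 53.3. CTSB shares reads with an alternate copy, and its log2 change was −4.12 on the main copy and −1.66 (SE 0.04) when both were summed.

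Respiratory, heat shock and ribosomal genes moved both ways. Nuclear-encoded oxidative phosphorylation genes had 8 risen and 10 fallen of 25, or 8 and 11 when adjusted over the list alone (camera adjusted p = 0.927, directed down, with a median of 0.03 and a mean of −0.01). ATP5F1B rose from 18869 ± 91.1 to 22836 ± 550, and CYC1 fell from 2021 ± 84.8 to 1351 ± 51.8 (SD, n = 3). Of 14 heat shock genes, 5 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.832, directed up, with a median of 0.08 and a mean of −0.03). HSPA8 rose from 13198 ± 571 to 20579 ± 281, and HSP90AB1 fell from 42864 ± 326 to 31750 ± 218. Of 29 cytosolic ribosomal protein genes, 9 rose and 12 fell, also when adjusted over the list alone (camera adjusted p = 0.927, directed up, with a median of 0.03 and a mean of −0.01). RPL10 rose from 10711 ± 325 to 14735 ± 364, and RPS2 fell from 29869 ± 359 to 18821 ± 329. None of the mitochondrially encoded genes was listed in the deposited table, so 0 were measured.

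Genes of secreted liver proteins were near the floor in both groups, while some metabolic and fetal liver markers were abundant. Albumin (ALB) and alpha-fetoprotein (AFP), secreted in quantity by hepatocytes and fetal liver, each had 0 reads in control and 1 read over the 3 libraries labelled knockout. Of 15 genes of secreted plasma proteins, 3 (APOA2, APOH and TTR) were not listed in the deposited table, and the highest group mean of the other 12 was 12.0. Of 24 measured hepatocyte markers, 5 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.561, directed up, with a median of 0.11 and a mean of −0.29). CPS1, the entry enzyme of the urea cycle, fell from 4487 ± 141 to 3.68 ± 1.79 (SD, n = 3), and ASS1, of the same cycle, rose from 9793 ± 159 to 16151 ± 378. Of 20 fetal liver and progenitor markers, 3 rose and 8 fell, also when adjusted over the list alone (camera adjusted p = 0.145). PEG10 fell from 10720 ± 371 to 1715 ± 9.61. THY1 fell from 2285 ± 42.7 to 3 reads over the group, a ratio of 2220 with a 95% counting interval from 758 to 10800.

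Among markers of other cell types that passed, more fell than rose in the libraries labelled knockout. Fibroblast and stellate cell markers, a list that shares COL1A1 with the mesenchymal list, had 5 fallen and 2 risen of 14, or 4 and 2 when adjusted over the list alone (camera adjusted p = 0.295). FAP fell from 102 ± 3.24 to 0 reads (SD, n = 3), at least 99.3-fold, and COL1A1 rose from 1485 ± 19.3 to 3111 ± 158. Endothelial markers had 3 fallen and 2 risen of 14, also when adjusted over the list alone (camera adjusted p = 0.734), with PECAM1 down from 123 ± 15.5 to 3.01 ± 3.69 and ERG up from 79.3 ± 12.6 to 246 ± 15.7. Kidney line and neuronal markers had 4 fallen and 1 risen of 8, also when adjusted over the list alone (camera adjusted p = 0.233), with MAP2 down from 95.7 ± 2.53 to 1.76 ± 0.732 and SNAP25 up from 103 ± 23.3 to 311 ± 6.60.

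Changes formed runs along the chromosomes, a comparison chosen after the values were seen. In 135 of 11365 windows of 21 neighbouring genes, the median log2 change lay beyond 0.91, the limit from 200 shuffles of gene order. These windows formed 9 runs, 6 lower and 3 higher in the libraries labelled knockout. The longest, on chromosome 4 from PDGFC to ING2, covered 26.8 Mb with a median log2 change of −1.10 over 39 genes. On chromosome 19, 58 genes from ABCA7 to TLE6 had a median of −1.21, and 34 genes from ZNF841 to EPS8L1 had a median of 0.83. In the 2 higher runs of chromosome 19, 44 zinc finger genes had a median of 1.03 and the 24 other genes a median of 0.03. Nearly all of these other genes lay at the ends of the runs. Outside the runs of that chromosome, 115 zinc finger genes had a median of 0.51 and 531 other genes a median of −0.16. On chromosome 13, 22 genes from ABHD13 to ADPRHL1 had a median of 0.90. KEAP1, whose product keeps NRF2 low, lies within a lower run (chromosome 19, 10486125 to 10503356, GRCh38) and went from 362 in the authors' deposited table to 0 reads, at least 352-fold lower. Its neighbour S1PR5 went from 294 reads to 1, a ratio of 273 with a 95% counting interval from 48.6 to 10800. The 20 genes around this pair had a median log2 change of −1.06, with 19 of them below 0.

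**Figure D4:**
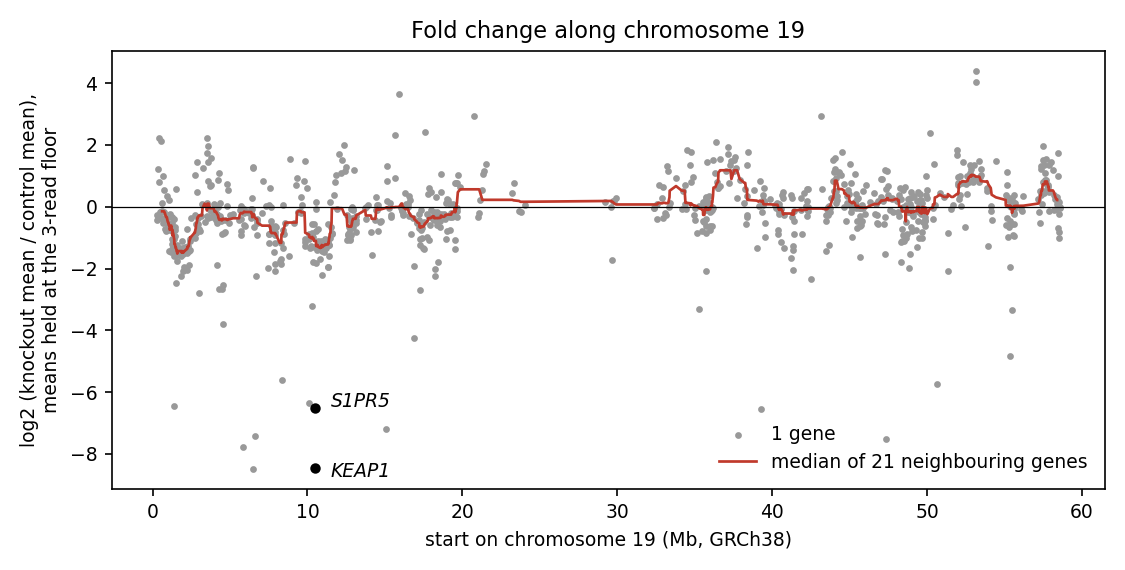
Log2 ratio of group means (libraries labelled knockout over control, y) against gene start on chromosome 19 (x, Mb, GRCh38), with a point for each gene and a line for the median of 21 neighbouring genes. KEAP1 and S1PR5 lie far below 20 neighbours whose median is −1.06.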

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

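The alternatives for genes, other than the threshold of 0.01 and the fold minimum, and those for lists with summed copies were chosen after seeing the data. Voom values for lists were planned for counts, but the reads they ran on were recovered after seeing the data. The count of 9472 changed genes was 8406 at an adjusted p of 0.01, 2979 with a log2 change of at least 1 as well (fewer by construction), 9279 with a mean of at least 10, and 8663 to 10478 under the limma settings on recovered libraries with all 6 libraries. Leaving out each library in turn gave 9819 to 9989. All 9470 authors' calls with recovered reads were also called by limma with default settings, 0 in the opposite direction. For 89 named genes, 1418 alternative values kept their direction and side of the threshold. The exceptions were both ORAI2, at 0.01 (adjusted p = 0.0468) and without library C labelled knockout (log2 change −0.12). STIM1 stayed higher in the libraries labelled knockout, with log2 changes from 0.51 to 0.67. Of 35 lists, 5 were called. With an estimated correlation 0 were called, by fry 30, and with the stricter filter 8, of 32 tested, which added calcineurin-NFAT, hypoxia and NF-kB. With voom values 7 were called, which added hypoxia and glycolysis. Leaving out each library in turn called 4 to 6. The estimated correlation was 0.004 for mesenchymal and −0.023 for cell cycle genes, below the preset 0.01. A higher correlation between members is thus argued against as what removed these calls. It was 0.015 for the ATF4, 0.048 for the interferon and 0.05 for the epithelial list. Fry makes no comparison with other genes. Other causes were not tested. Fry turned fatty acid synthesis downwards (median log2 change 0.07, adjusted p = 0.0253), where camera gave up, and the cause was not tested. No paired analysis was possible because the recovered libraries carry no replicate number, so the planned block was not run. Normalization by TMM or DESeq2 factors within edgeR and the DESeq2 Wald test were not run either. Depth limits genes near the floor of 3 reads, such as ALB and AFP, where no difference was detectable.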

Other observations

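All tests of explanations below were chosen after the result was seen, except the test of GC content and gene length. Of 319 KEGG pathways tested with camera, 0 passed. The lowest adjusted p was 0.485, shared by Hippo signaling (144 genes, up, unadjusted p = 0.00237), thiamine metabolism (14 genes, up), aminoacyl-tRNA biosynthesis (43 genes, down) and steroid hormone biosynthesis (29 genes, down). Among genes chosen after their values were seen, in the authors' deposited table, CGA, the alpha subunit of chorionic gonadotropin, rose from 5441 to 16351, and the placental alkaline phosphatase ALPP from 629 to 4741. The limma count for the real grouping of the 6 recovered libraries was 10430 genes (10766 unadjusted), and 1 of the 10 splits, the real grouping, reached it. The other splits gave 0 genes by limma, and at most 97 at an unadjusted p under 0.05, but 10 splits are too few for a share under 0.05. Each of the other splits also put libraries of both groups on each side. The difference between the groups then counted as spread within a side, so few calls were bound to follow, and the splits cannot exclude chance.

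STIM1 reads were higher in the libraries labelled STIM1 knockout. Extra copies of the region are argued against, since the 20 neighbouring genes had a median log2 change of −0.05, with an upper quartile of 0.43. An exchange of the group labels as a whole cannot be told apart from an edit that leaves the transcript, since control held 66.1% of the mean labelled knockout and gene totals show neither the edited exon nor the protein. Whether raised STIM1 transcript is a response to the edit was not tested.

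Genes of secreted plasma proteins were near 0 in both groups, although Hep3B is known as a line that makes liver plasma proteins. Reads lost to alternate copies are argued against, since the highest group mean of the 12 plasma protein genes listed was 12.0 with all copies summed, while 3 others were not listed. These levels go against what is known of the labelled line. A loss of their expression in culture and cells of another line were not tested and cannot be told apart here, and the gene totals identify no line. Both groups share the pattern, and no biological explanation was tested.

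Complete losses and runs of neighbouring genes marked the libraries labelled STIM1 knockout. Whether DNA was gained over the 2 higher runs of chromosome 19 stays open. Genes there other than zinc finger genes had a median log2 change of 0.03 (upper quartile 0.59). Nearly all of them lay at the ends of the runs, outside the centres of the windows beyond the limit, so they cannot decide it. The exception, ERVV-2, had a log2 ratio of 1.36. Trends with GC content and length are argued against, since 119 of 131 windows stayed beyond the limit after their removal. The limits were 0.86 before and 0.85 after. The long segments seen as runs do not account for most of the complete losses, of which 3 of 45 lie in the runs. Of all ordered genes, 2.7% lie in the runs. Shorter segments were not tested as a cause of these losses, since a median over a window of neighbouring genes cannot show a loss of only a few genes. DNA lost or gained over the other runs stays open too. In 6 of 7 both quartiles lay on the side of the median, but the runs were found by that shared direction. Zinc finger genes in the lower runs of chromosome 19 had a median of −0.01 against −1.22 for the others. These zinc finger genes also lay at the ends of the runs, so they cannot decide it. Whether KEAP1 loss raised NRF2 targets also stays open, at an adjusted p of 0.275 for the list, and an effect of STIM1 knockout cannot be separated in this design from a difference between the clones or passages behind the groups.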
